A study of Homo sapiens with 12 samples.

How the data were processed

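RNA from 12 samples of the human breast cancer cell line MDA-MB-231 was measured on Clariom S human arrays, which read most genes with 1 transcript cluster each. Cells were grown in serum-supplemented RPMI medium and RNA was purified with Qiazol and RNeasy columns, per the labels' protocols. The samples were 4 of wild-type cells, 2 each of the JMJD6 knockout lines KO5 and KO6, and 2 each of the scramble lines 3 and 7. For scramble 7 replicate 2 the title names a knockout, while the description and the source name give scramble 7; it was analysed as scramble 7.

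The deposited values are log2 signals from robust multi-array averaging (RMA) in the Affymetrix Expression Console, per the submitters' processing notes, with no versions given. These notes also name the mouse build mm10, which does not match a human array and was not used. As commonly run, RMA subtracts background, quantile-normalizes probe signals between arrays and summarises the probes of a cluster; under such scaling a change in total RNA per cell is not visible. No further normalization was applied. The table held 27189 rows, of which 21448 transcript clusters were tested. The other 5741 were left out as controls, 2555 with purely numeric names, whose role is not given in the sources used here, and 3186 with other control names. Of the tested clusters 17709 have 1 gene symbol in the platform annotation, 0 have several and 3739 are unnamed here. A gene with several clusters was represented by that with the highest mean. Every column of per-sample values belonged to a sample of the series.

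The background floor of each array was the 95th percentile of 612 negative control rows; it ranged from 6.03 to 6.25 with a mean of 6.13. Where all arrays of an arm lay under it, a fold is given as a lower bound, and none where the bound is under 1 or both arms lay under it. Signal strength over this floor takes the place of sequencing depth, and dim clusters have compressed differences.

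Tests used limma 3.58.1 in R 4.3.3. Linear models on the log2 values had the 3 arms (knockout, scramble, wild type) as fixed terms and the line as a random block through duplicateCorrelation, which estimated a correlation of -0.02 within lines, with 9 residual and 4.87 prior degrees of freedom. All arms shared 1 estimate of the spread. Two-sided p-values from eBayes were adjusted by Benjamini-Hochberg over the 21448 clusters, with a threshold of 0.05. The comparisons were knockout against scramble, knockout against wild type, scramble against wild type, and an intersection-union test for a difference of the same sign from both controls, which takes the larger p and stays valid although the knockout arrays are shared. KO6 against KO5 and scramble 7 against scramble 3 came from a model with the 5 lines as fixed terms and 7 residual degrees of freedom. Shared and separate differences of the knockout lines were described by correlations between line pairs with no array in common.

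Genes are named by a rule: the 12 largest rises and 12 largest falls among called clusters with 1 gene symbol and no overlap between arms, for comparisons between lines up to 8 per direction, filled to 5 with the smallest p where fewer passed, JMJD6 always, and up to 4 members with the smallest p from each gene list described. The 50 gene lists cover pathways, complexes, metastasis genes of this cell line, markers of other cell types and transcripts that follow RNA quality, and hold 1118 entries, of which 984 were measured. Each list was tested with limma's cameraPR on the moderated t, with a preset inter-gene correlation of 0.01, with an estimated one and on ranks, adjusted over the 50 lists. A negative estimate counted as no correlation. An estimate under 0.01 makes the test more lenient than the preset one. The designs, the rule, the lists and all alternatives but the last 3 listed here were fixed before the data were examined. Neighbouring genes were compared in windows of 50 genes in the order of GRCh38.p14, used only for names and neighbours; no coordinates are given because the build behind the arrays was not matched. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

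The procedure was tested on simulated data with 21448 clusters. For knockout against scramble it recovered 78%, 94%, 100% and 100% of changes of 0.5, 1, 2 and 4 on the log2 scale, with 13 false calls. For knockout against wild type it recovered 76%, 96%, 100% and 100%, with 26 false calls, for both controls together 64%, 94%, 100% and 100%, with 2 false calls, and for KO6 against KO5 36%, 84%, 98% and 100%, with 11 false calls. Each size of change was given to 50 clusters. Except for both controls together, false calls were therefore a larger share of all calls than the threshold of 0.05, most so against wild type. Of 200 simulated lists without a change, 8 had a p under 0.05. The simulated noise was drawn independently for each cluster and array. It held no line differences, no correlation between genes and no deviating arrays, so these rates do not cover data with such features.

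Alternatives covered the treatment of lines (no block, fixed, averaged, each left out), the replicate number as a block, median centring, quantile normalization, leaving out dim or unnamed clusters, a trended and robust eBayes, a minimum difference of 1 on the log2 scale, and leaving out each array in turn. Added after the data were seen were array quality weights, leaving out 3 arrays that deviate together, and leaving out the genes of shifted windows.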

Results

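Gene expression was measured on 12 Clariom S human arrays, each hybridised with RNA from MDA-MB-231, an established triple-negative human breast cancer cell line. The design asks what changes in these cells when JMJD6, a Jumonji-domain 2-oxoglutarate-dependent oxygenase, is deleted by CRISPR-Cas9. There were 2 knockout lines, KO5 and KO6, and 2 lines edited with a scramble control, scramble 3 and scramble 7, with 2 arrays per line, and 4 arrays of unedited wild-type cells. The knockout, scramble and wild-type arms therefore held 4 arrays each (n = 4 arrays), from 2 knockout lines, 2 scramble lines and the wild-type cells. These numbers limit the precision of every value given here. With an estimated correlation of -0.02 within lines, the model treated arrays of a line nearly as independent samples. The SE are therefore too small if lines differ as a whole. The labels do not say whether a line is a clone or a pool, or whether arrays of a line came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Scramble 7 replicate 2 has a title naming it as a knockout and 2 other labels naming it as scramble 7, and it was kept in scramble 7. The 21448 transcript clusters tested ranged from 3.51 to 13.95 on the log2 scale, and 18.8% of them lay under the background floor on all 12 arrays.

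The targeted transcript was examined before all others. JMJD6 signal on the knockout arrays was 9.48 and 9.45 in KO5 and 9.28 and 9.40 in KO6, while all scramble and wild-type arrays lay between 10.21 and 10.46. The arm means were 9.40 ± 0.09 in the knockout, 10.35 ± 0.09 in scramble and 10.24 ± 0.05 in wild type (log2, SD, n = 4). JMJD6 fell by 0.95 against scramble (SE 0.07, limma adjusted p = 5.22e-07), which is 48.3% lower, and by 0.84 against wild type (SE 0.07, limma adjusted p = 1.61e-06), which is 44.1% lower. The scramble and wild-type arms differed by 0.11 (SE 0.07, limma adjusted p = 0.508). Scramble 7 replicate 2 read 10.30, on the side of the controls. The position of the JMJD6 probes relative to the edited part of the gene is not given in the sources used here, so the remaining signal does not measure functional JMJD6.

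**Figure D1:**
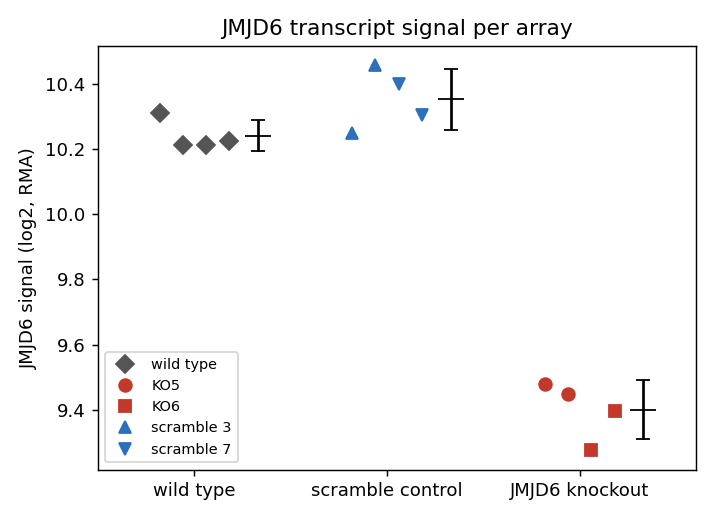
JMJD6 signal (log2, RMA) on each of the 12 arrays, by arm, with marker shapes for the lines and black bars for the arm mean ± SD (n = 4). The knockout arrays lie between 9.28 and 9.48, under all control arrays, which lie between 10.21 and 10.46.

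The knockout arrays stood apart from both control arms over the whole transcriptome. The principal component with the largest share of variance, 44.0%, placed the knockout arrays between 23.2 and 29.3 and all control arrays between -25.5 and -9.98. The next component, 22.2% of the variance, ran mainly within arms: scramble 3 replicate 1 lay at 33.4, KO6 replicate 1 at 17.3 and wild type replicate 1 at 14.9, and all other arrays were at 0.36 or lower. Pairs of 1 KO5 and 1 KO6 array differed with an SD of 0.15 to 0.22 across transcript clusters. The same SD was 0.16 between the KO5 arrays, 0.21 between the KO6 arrays, 0.17 between the scramble 7 arrays and 0.35 between the scramble 3 arrays. Pairs of a knockout and a scramble array differed with an SD of 0.32 to 0.46, and pairs of a scramble and a wild-type array with 0.17 to 0.39.

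**Figure D2:**
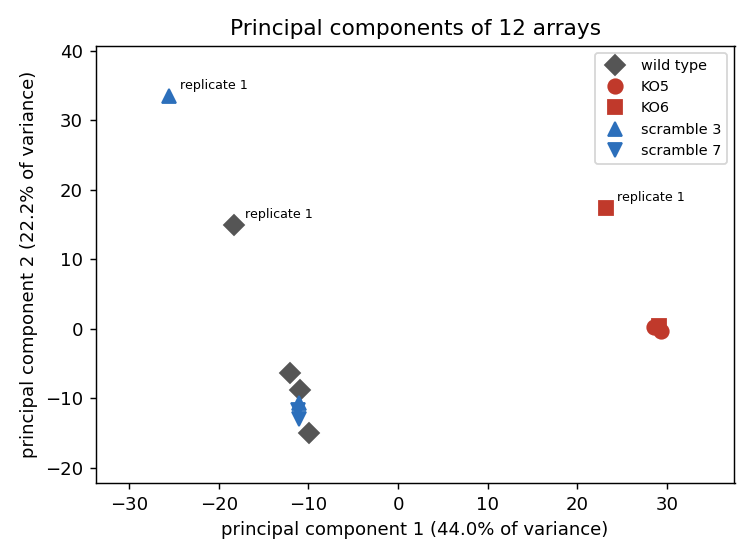
Position of the 12 arrays on the leading principal components of the log2 values, with the share of variance on each axis; colours mark the arms and shapes the lines. The knockout arrays lie between 23.2 and 29.3 on the horizontal axis, and replicate 1 of scramble 3, KO6 and wild type stand apart on the vertical axis.

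Knockout was compared with scramble to ask what differs from cells taken through editing without the target. The largest measured rise and fall were in MAGEC2 and PAGE5, cancer-testis genes of the X chromosome. MAGEC2 rose by 5.08 (SE 0.09), from 5.26 ± 0.13 in scramble to 10.34 ± 0.11 in the knockout, at least 18.2-fold, and MAGEC1 rose by 4.49 (SE 0.09), at least 17.5-fold. PAGE5 fell by 5.66 (SE 0.15), from 11.85 ± 0.10 to 6.19 ± 0.40 with 1 of 4 knockout arrays over the background floor, PAGE2 fell by 4.02 (SE 0.11), PAGE2B fell by 2.74 (SE 0.12) and SSX1 fell by 2.36 (SE 0.13), the last at least 3.52-fold. The SPANX genes SPANXD, SPANXA2 and SPANXC rose by 3.29, 3.27 and 3.26 (SE 0.07 each). Probes of SPANX, PAGE and MAGE genes can bind near-identical paralogs, so it is uncertain which member of each family produced the signal. Among adhesion genes, the cadherins CDH18 and CDH10 rose by 4.39 (SE 0.08, at least 14.98-fold) and 3.05 (SE 0.12, at least 3.42-fold). TIMP3, an inhibitor of matrix metalloproteinases, rose by 4.03 (SE 0.13, 16.4-fold), and FABP5, a fatty acid-binding protein, rose by 3.99 (SE 0.17), with 3 of 4 scramble arrays over the floor. CMKLR1, the receptor of chemerin, rose by 3.96 (SE 0.12, at least 13.8-fold), and the membrane proteins MXRA8 and MAL2 rose by 3.28 and 3.11 (SE 0.13 each; MXRA8 with 1 of 4 scramble arrays over the floor, MAL2 at least 2.49-fold). LCP1, the actin-bundling protein L-plastin, fell by 4.38 (SE 0.09), from 11.41 ± 0.10 to 7.02 ± 0.20, which is 20.9-fold. The cytokine gene IL1B fell by 2.70 (SE 0.09, 6.51-fold), and the transporters SLCO4C1 and SLC14A1 fell by 3.03 (SE 0.15, at least 5.29-fold) and 2.81 (SE 0.08), SLC14A1 with 2 of 4 knockout arrays over the floor. TGIF2LX, a homeobox gene, fell by 2.81 (SE 0.17, at least 2.34-fold), TMPRSS15 fell by 2.39 (SE 0.11, at least 2.12-fold), PLCB1 fell by 2.34 (SE 0.11, at least 3.57-fold) and CLIC6 fell by 2.19 (SE 0.13). In each of these genes every knockout array lay on one side of every scramble array, and the highest limma adjusted p among them was 6.29e-08, that of TGIF2LX. A bound written as at least N-fold sets the mean of the brighter arm against, on each array of the dimmer arm, the higher of the background floor and the measured value.

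**Figure D3:**
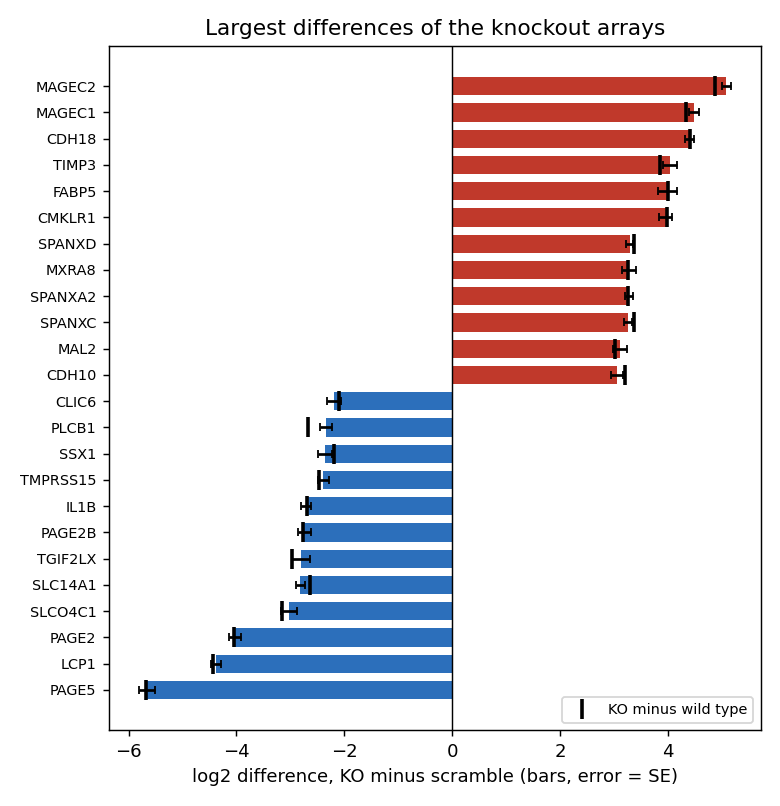
Log2 difference of the knockout from scramble for the 12 largest rises and 12 largest falls (bars, n = 4 per arm; error bars are SE), with the knockout minus wild-type difference as a vertical tick. The bars run from -5.66 for PAGE5 to 5.08 for MAGEC2, and each tick lies on the same side of 0 as its bar.

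In all, 3682 of 21448 transcript clusters differed between knockout and scramble in limma at an adjusted p of 0.05, 1950 higher and 1732 lower, and 197 of these by at least 1 on the log2 scale, 128 higher and 69 lower. The knockout arrays did not overlap the scramble arrays at 4644 clusters, 21.7% of those tested. Chance gives 2.86% if all arrays are exchangeable, which they are not if lines differ as a whole. Scramble and wild-type arrays did not overlap at 1863 clusters, 8.69%. The count of clusters called between knockout and scramble was 1827 without scramble 3 replicate 2 and 2353 without KO6 replicate 2.

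Immediate early genes, which growth factors and stress induce within minutes, were lower in the knockout. Of 21 measured members 14 fell, none rose and 7 were not called, and adjusted over the list alone the count was also 14. EGR1 fell by 1.48 (SE 0.08), FOSB fell by 1.46 (SE 0.09), IER3 fell by 0.90 (SE 0.07) and DUSP1 fell by 0.85 (SE 0.07). The list test, limma's cameraPR with a preset correlation of 0.01, gave an adjusted p of 3.19e-16, and the adjusted p = 2.36e-06 with an estimated correlation. A list of short-lived and mitochondrial transcripts that follow RNA quality had 4 measured members, all of them also immediate early genes; IER2, FOS and JUN fell by 0.57, 0.67 and 0.71 and MYC stood at 0.09 (limma adjusted p = 0.00265 for the list; adjusted p = 0.121 with an estimated correlation). Genes fixed as feedback targets of the ERK pathway went the same way, 11 of 19 lower and 3 higher, counts that did not change when adjusted over the list alone. The phosphatase genes DUSP4, DUSP5 and DUSP6 fell by 0.57, 0.55 and 0.41 (SE 0.07, 0.07 and 0.06), and HBEGF fell by 0.66 (SE 0.09). That list had a limma adjusted p of 0.00194, and adjusted p = 0.149 with an estimated correlation. Among NF-kB targets and inflammatory cytokines, 8 of 28 fell and 5 rose, or 12 and 6 adjusted over the list alone, with IL1B, IER3, PTGS2 (-0.86, SE 0.08) and NFKBIA (-0.52, SE 0.07) lower. This list had a limma adjusted p of 1.99e-04, and adjusted p = 0.0285 with an estimated correlation. Of its 28 members 5 lie in windows of neighbouring genes that shifted in both knockout lines, CXCL8, CXCL1, CXCL3, CXCL2 and NFKB1. Without the genes of such windows the limma adjusted p of the list was 1.22e-04. A set of genes linked to bone metastasis of MDA-MB-231 also fell, 5 of 11 lower and 1 higher (6 and 1 adjusted over the list alone), including the collagenase MMP1 (-1.37, SE 0.07), the chemokine receptor CXCR4 (-0.92, SE 0.09) and SRGN (-0.67, SE 0.07). Its limma adjusted p was 1.06e-05, and adjusted p = 4.41e-06 with an estimated correlation; 1 of its members, DUSP1, is also an immediate early gene. The immediate early, NF-kB and bone metastasis lists were the 3 of 50 whose calls held with an estimated correlation. For bone metastasis that test gave a lower adjusted p than the preset one, so it was no stricter check there. On ranks the bone metastasis call was lost (limma adjusted p = 0.0877), as was that of the RNA-quality list (0.10).

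Genes of the G2/M phase and mitosis were higher in the knockout: 22 of 30 rose and none fell, or 23 adjusted over the list alone. CENPE, a kinetochore motor, rose by 0.86 (SE 0.08), CDCA8 by 0.81 (SE 0.11), DLGAP5 by 0.52 (SE 0.07) and KIF23 by 0.50 (SE 0.07); the limma adjusted p of the list was 2.69e-09, and adjusted p = 0.0555 with an estimated correlation. Of the 30 members 3 lie in windows of neighbouring genes that were higher in both knockout lines, CENPE on chromosome 4 and CDC20 and KIF2C on chromosome 1; without the genes of shifted windows the limma adjusted p was 1.14e-07. Of 35 E2F targets and DNA replication genes, 7 rose and none fell (10 adjusted over the list alone), with CDC6 at 0.54 (SE 0.08), CLSPN at 0.62 (SE 0.10) and RFC3 at 0.50 (SE 0.10). This list had a limma adjusted p of 0.0436, adjusted p = 0.745 with an estimated correlation, 0.134 without scramble 3 replicate 1, and was also lost without KO5 replicate 2. Of 37 interferon-stimulated genes 16 rose, 2 fell and 19 were not called, or 18 rose and 3 fell adjusted over the list alone. SAMD9 rose by 1.00, IFI27 by 0.98, OAS1 by 0.95 (SE 0.08 each; OAS1 with 1 of 4 scramble arrays over the floor) and IFIT2 by 0.87 (SE 0.07); the limma adjusted p was 1.81e-05, and adjusted p = 0.121 with an estimated correlation. Cholesterol synthesis and uptake genes rose at 13 of 19 members and fell at 1, the same counts adjusted over the list alone. The synthesis enzymes MSMO1 and CYP51A1 rose by 0.61 (SE 0.08) and 0.59 (SE 0.09), INSIG1 rose by 0.46 (SE 0.06) and the isomerase EBP fell by 0.59 (SE 0.08), EBP lying in a window of X chromosome genes that was lower in both knockout lines. MSMO1 was lower in scramble than in wild type (-0.54, SE 0.08, limma adjusted p = 0.0320), and the knockout stood at 0.066 (SE 0.08, limma adjusted p = 0.673) from wild type. CYP51A1 was not called against wild type either (0.27, SE 0.09, limma adjusted p = 0.0584). The limma adjusted p of that list was 5.64e-04, and adjusted p = 0.222 with an estimated correlation.

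Of 16 measured protocadherins, 3 rose and 2 fell (3 and 3 adjusted over the list alone): PCDH7 rose by 2.64 (SE 0.14), PCDH9 by 1.32 (SE 0.10) and PCDH1 by 1.32 (SE 0.11), and PCDH18 fell by 0.60 (SE 0.09). The limma adjusted p was 0.0360, adjusted p = 0.0555 with an estimated correlation, 0.0765 without scramble 7 replicate 1, and the call was also lost without KO5 replicate 1. MHC class I antigen presentation genes fell at 7 of 16 members and rose at 1, or 9 and 1 adjusted over the list alone, with the immunoproteasome subunits PSMB9 and PSMB8 lower by -0.40 (SE 0.08) and -0.33 (SE 0.06). That call (limma adjusted p = 0.0491) had an adjusted p = 0.478 with an estimated correlation and was lost on leaving out any of 8 of the 12 arrays, namely wild type 2 and 3, KO5 replicate 1, KO6 replicate 1 and each scramble array, with a highest value of 0.0825 without scramble 7 replicate 2. The leukocyte markers, fixed as a sign of another cell type, had a limma adjusted p of 0.0156, adjusted p = 0.222 with an estimated correlation, and 0.0812 without scramble 3 replicate 1. Only LCP1 (-4.38) and the T-cell gene CD3D (1.49, SE 0.15, at least 1.96-fold) were called among its 16 members, and the counts adjusted over the list alone were the same. On ranks the protocadherin and leukocyte calls were lost (limma adjusted p = 0.504 and 0.918). Of 19 measured cancer-testis genes 2 rose and 3 fell, the same counts adjusted over the list alone; the list had a median of -0.04, a mean of -0.15 and a test direction upwards, with a limma adjusted p of 0.626. Of 6 measured genes beside JMJD6 on its chromosome 1 rose, METTL23 by 0.26 (SE 0.08, limma adjusted p = 0.0433), and none fell, or 1 and 1 adjusted over the list alone, with a median of -0.01 and a mean of 0.03 (limma adjusted p = 0.985 for the list). METTL23 lost its call without wild type 1, either KO5 array, either KO6 array or scramble 3 replicate 2, with a highest limma adjusted p of 0.121 without KO6 replicate 2.

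**Figure D4:**
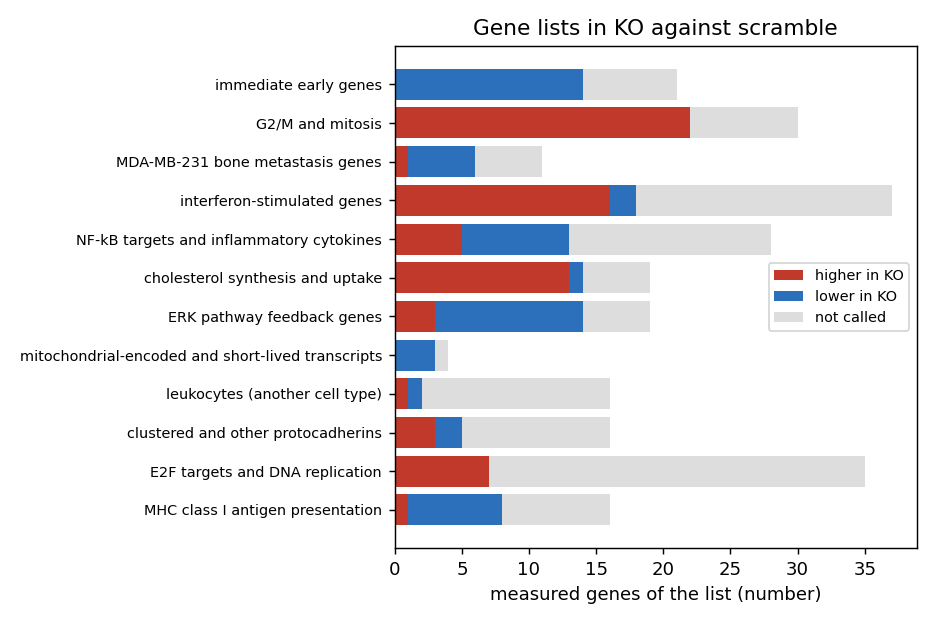
Number of measured genes in each of the 12 gene lists past the list test in knockout against scramble, divided into higher (red), lower (blue) and not called (grey). Immediate early genes hold 14 lower and no higher members, and G2/M genes 22 higher and no lower members.

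Against the unedited wild-type cells, MAGEC2 and PAGE5 again had the largest measured rise and fall. MAGEC2 rose by 4.87 (SE 0.09, at least 18.8-fold), CDH18 by 4.42 (SE 0.08, at least 15.5-fold), MAGEC1 by 4.33 (SE 0.09, at least 18.0-fold), FABP5 by 4.00 (SE 0.17), CMKLR1 by 3.97 (SE 0.12) and TIMP3 by 3.85 (SE 0.13). Of the 4 wild-type arrays, 2 lay over the floor for FABP5, CMKLR1 and MXRA8. SPANXC, SPANXD, SPANXA2 and SPANXA1 rose by 3.38, 3.37, 3.27 and 3.12, and MXRA8 and CDH10 by 3.25 and 3.19 (CDH10 at least 3.53-fold). PAGE5 fell by 5.69 (SE 0.15), LCP1 fell by 4.43 (SE 0.09, 21.5-fold) and PAGE2 fell by 4.05 (SE 0.11). PAGE2B fell by 2.76, IL1B fell by 2.68 and SLC14A1 fell by 2.64. Genes under the floor on all knockout arrays were SLCO4C1, which fell by 3.16 (at least 5.82-fold), TGIF2LX, which fell by 2.97 (at least 2.61-fold), PLCB1, which fell by 2.67 (at least 4.48-fold), and TMPRSS15, which fell by 2.48 (at least 2.25-fold). SSX1 fell by 2.18 (at least 3.12-fold) and NSUN7 fell by 2.12 (at least 2.22-fold), likewise under the floor in the knockout. The SE of the genes given here without one lay between 0.07 and 0.17. The highest limma adjusted p among these genes was 5.26e-08, that of SSX1, and no knockout array overlapped a wild-type array in any of them. In all, 3319 clusters differed in limma, 1841 higher and 1478 lower, 202 of them by at least 1 on the log2 scale. The knockout and wild-type arrays did not overlap at 5065 clusters, 23.6%. Chance gives 2.86% if all arrays are exchangeable, and the share for scramble against wild type was 8.69%. The count of called clusters was 1191 without scramble 3 replicate 2, 1976 without KO6 replicate 2 and 5741 without scramble 3 replicate 1. The scramble arrays enter this comparison through the shared estimates of the spread and of the correlation within lines. That correlation was 0.29, 0.05 and -0.11 with these arrays left out in turn, against -0.02 with all arrays.

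Of the 50 lists, 17 passed the list test against wild type. With an estimated correlation 9 held, though for bone metastasis and epithelial genes that test gave a lower adjusted p and was no stricter check. On ranks 6 of these 9 were lost in limma: NF-kB (adjusted p = 0.0897), RNA quality (0.0847), protocadherins (0.813), epithelial (0.253), mesenchymal (0.0878) and luminal (0.796). Immediate early genes fell at 15 of 21 members, 16 adjusted over the list alone (limma adjusted p = 9.33e-18; adjusted p = 5.57e-07 with an estimated correlation), and G2/M genes rose at 18 of 30, 20 adjusted over the list alone (limma adjusted p = 1.30e-08; adjusted p = 0.0423 with an estimated correlation). Bone metastasis genes fell at 6 of 11 and rose at 1, 7 and 2 adjusted over the list alone, with MMP1 at -1.47 (SE 0.07) (limma adjusted p = 1.77e-05; adjusted p = 9.45e-06 with an estimated correlation). NF-kB targets and cytokines fell at 9 of 28 and rose at 4, 11 and 4 adjusted over the list alone (limma adjusted p = 2.95e-04; adjusted p = 0.0237 with an estimated correlation). The RNA-quality list again had 3 of 4 members lower, also 3 adjusted over the list alone, all 4 being immediate early genes too (limma adjusted p = 2.95e-04; adjusted p = 0.0423 with an estimated correlation). Protocadherins rose at 3 of 16 and fell at 2, the same counts adjusted over the list alone, with a median of -0.01 and a mean of 0.27 (limma adjusted p = 0.0304; adjusted p = 0.0423 with an estimated correlation), a call lost without KO5 replicate 1 (0.0540). The epithelial, mesenchymal and luminal lists, given next, did not pass the list test against scramble. Epithelial adhesion genes rose at 6 of 29 members and fell at none, also 6 adjusted over the list alone, with a median of 0.01 and a mean of 0.24. EPCAM rose by 1.11 (SE 0.15), CD24 by 1.22 (SE 0.11, at least 1.29-fold) and the protease inhibitor SPINT2 by 0.74 (SE 0.08), beside MAL2 (limma adjusted p = 0.00852; adjusted p = 0.00487 with an estimated correlation). Mesenchymal genes rose at 7 of 22 and fell at 2, or 8 and 2 adjusted over the list alone, with the transcription factor SNAI2 at 0.96 (SE 0.08), the matrix protein TNC at 1.27 (SE 0.12) and the receptor kinase AXL at 0.67 (SE 0.07) (limma adjusted p = 0.0232; adjusted p = 0.0237 with an estimated correlation). Markers of luminal breast epithelium rose at 6 of 18 and fell at 2, counts unchanged when adjusted over the list alone, with TFF1 at 1.47 (SE 0.09), AGR2 at 1.15 (SE 0.09) and CA12 at 1.07 (SE 0.11). That list had a median of -0.03 and a mean of 0.21 (limma adjusted p = 0.0419; adjusted p = 0.0423 with an estimated correlation), and its call was lost without scramble 3 replicate 1 (0.0795) and without KO6 replicate 1.

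The other 8 lists past the test against wild type were lost with an estimated correlation, and the p53 and leukocyte lists also on ranks (limma adjusted p = 0.108 and 0.856). Among them, the amino acid response, p53 and histone lists did not pass the list test against scramble. Genes of the ATF4 and amino acid response rose at 10 of 26 and fell at 2, 12 and 2 adjusted over the list alone (limma adjusted p = 0.00853, and adjusted p = 0.0651 with an estimated correlation). The glutamine transporter SLC1A5 rose by 0.86 (SE 0.08), SLC3A2 rose by 0.55 (SE 0.07) and ATF3 fell by 0.88 (SE 0.08). Of 22 p53 targets 7 rose and 1 fell, 8 and 1 adjusted over the list alone, led by GADD45A at 0.95 (SE 0.07), which lies in a window of chromosome 1 genes higher in both knockout lines (limma adjusted p = 0.0486; adjusted p = 0.157 with an estimated correlation). The p53 call was lost on leaving out any of 8 arrays, namely wild type 1 and 2, both KO5 arrays, KO6 replicate 2, scramble 3 replicate 1 and both scramble 7 arrays, with a highest value of 0.0809 without KO5 replicate 1, and without the genes of shifted windows (0.178). Of 23 histone genes 4 rose, also 4 adjusted over the list alone, among them H1-2 at 0.66 (SE 0.08) (limma adjusted p = 0.0486; adjusted p = 0.512 with an estimated correlation). The histone call was lost without wild type 1 (0.172), KO5 replicate 1, KO6 replicate 1 or scramble 3 replicate 1. Interferon-stimulated genes rose at 14 of 37 and fell at 2, 17 and 4 adjusted over the list alone (limma adjusted p = 1.77e-05; adjusted p = 0.0968 with an estimated correlation). ERK feedback targets fell at 8 of 19 and rose at 1, 9 and 2 adjusted over the list alone (limma adjusted p = 0.00222; adjusted p = 0.131 with an estimated correlation). Cholesterol genes rose at 8 of 19 and fell at 1, 11 and 1 adjusted over the list alone (limma adjusted p = 0.0307; adjusted p = 0.458 with an estimated correlation), a call lost without KO5 replicate 1 (0.0563). DNA replication genes rose at 10 of 35, 11 adjusted over the list alone (limma adjusted p = 0.0161; adjusted p = 0.587 with an estimated correlation), a call lost without wild type 1 (0.0524). Leukocyte markers rose at 2 of 16 and fell at 1, the same counts adjusted over the list alone (limma adjusted p = 0.0161; adjusted p = 0.199 with an estimated correlation).

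A test that asked for a difference of the same sign from both control arms found 2041 clusters at an adjusted p of 0.05 in limma, 1119 higher and 922 lower, 175 of them by at least 1 on the log2 scale, 115 higher and 60 lower. By the smaller of the 2 differences, MAGEC2 (4.87), CDH18 (4.39), MAGEC1 (4.33), FABP5 (3.99) and CMKLR1 (3.96) led the rises, and PAGE5 (-5.66), LCP1 (-4.38), PAGE2 (-4.02), SLCO4C1 (-3.03) and TGIF2LX (-2.81) the falls. MAGEC2, CDH18 and MAGEC1 lay under the floor on all control arrays and SLCO4C1 and TGIF2LX on all knockout arrays, and PAGE5, FABP5 and CMKLR1 on some arrays of the dimmer arms, so the order of these genes is not exact. JMJD6 was in this set (-0.84, limma adjusted p = 1.92e-06). The count was 786 without scramble 3 replicate 2, 1281 without KO6 replicate 2 and 2967 with scramble 3 replicate 1 left out.

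Scramble was compared with wild type to ask what editing and line derivation change without the target. Other differences between these cultures cannot be told apart from editing. Here 27 clusters differed in limma, 12 higher and 15 lower, against 3019 at an unadjusted p under 0.05, and none differed by 1 or more on the log2 scale. PPP1CB, a catalytic subunit of protein phosphatase 1, was higher by 0.71 (SE 0.10), followed by GPN3 (0.55, SE 0.09), MRPL4 (0.50, SE 0.07) and the histone gene H2BC12 (0.50, SE 0.08). SNX7 fell by 0.74 (SE 0.10), CHUK, a kinase of the NF-kB pathway, fell by 0.73 (SE 0.10), and RARS1 fell by 0.63 (SE 0.10). ARHGAP28 (0.56, SE 0.10) lay under the floor on every array, and VPS13A (-0.76, SE 0.12) on all scramble arrays and 2 of 4 wild-type arrays, so these differences measure no fold. The limma adjusted p of the genes named here was 0.0320, except 0.0473 for ARHGAP28, and the arrays of the arms did not overlap in any of them. No call of this comparison held against the omission of single arrays: the count was 0 without wild type 3, KO5 replicate 2, KO6 replicate 2 or scramble 3 replicate 2, 1 without wild type 1, 5 without wild type 2, 59 without KO6 replicate 1, 245 without scramble 7 replicate 2 and 593 without scramble 3 replicate 1. Of the 50 lists 6 passed the preset test and none with an estimated correlation. Oxidative phosphorylation genes had a median of 0.07 with no member called (3 of 29 adjusted over the list alone), with a limma adjusted p of 0.0216, and adjusted p = 0.718 with an estimated correlation. The histone (1 higher, 2 adjusted over the list alone), ribosomal protein (0 and 0), p53 (0, 1 adjusted over the list alone), cholesterol (1 lower, 4 adjusted over the list alone) and integrin (0, 1 adjusted over the list alone) lists had limma adjusted p-values of 0.0422, 0.0465, 0.0465, 0.0456 and 0.0465, and adjusted p = 0.718, 0.756, 0.288, 0.718 and 0.106 with an estimated correlation. The p53 and integrin calls were lost without the genes of shifted windows (0.115 and 0.0550), and on ranks the p53 (0.0878), histone and integrin (0.0612 each) and cholesterol (0.302) calls were lost. The number of lists was 0 without scramble 3 replicate 2 or scramble 7 replicate 2, 1 without wild type 1 or scramble 7 replicate 1, and 2 without wild type 3, KO5 replicate 2 or KO6 replicate 1.

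The knockout lines were compared with each other to see how far they differ. KO6 against KO5 gave 0 calls in limma, with a largest difference of 0.78 on the log2 scale. At an unadjusted p under 0.05 there were 508 of 21448 clusters, fewer than the share of 0.05 that chance gives. The shared spread includes scramble 3, whose arrays differed with an SD of 0.35 against 0.16 in KO5. The 0 calls therefore do not show that the knockout lines are alike. ADGRB3, under the floor on every array, had the smallest p (-0.70, SE 0.10, limma adjusted p = 0.401), and EN2, over it on 3 of 4 knockout arrays, stood at 0.62 (SE 0.17, limma adjusted p = 0.999). Scramble 7 against scramble 3 also gave 0 calls in limma and 1816 at an unadjusted p under 0.05, with a largest difference of 1.07. NCR3LG1 (0.62, SE 0.12) and ZNF782 (0.81, SE 0.16) had the smallest p, with a limma adjusted p of 0.569 and 2 and 3 of 4 scramble arrays over the floor. The 0 calls between the scramble lines did not hold without scramble 3 replicate 2, which leaves scramble 3 with 1 array. With no array shared, the log2 differences of KO5 from scramble 3 and of KO6 from scramble 7 correlated across the 21448 clusters with Pearson's r = 0.65 and Spearman's rho = 0.39, and with the scramble lines exchanged 0.79 and 0.61. KO6 minus KO5 and scramble 7 minus scramble 3 gave -0.33 and -0.34. By construction, their covariance is the difference between the covariances of the pairings given before. These values are therefore no separate baseline for the other correlations. These are correlations across genes, which are not independent replicates; r was 0.46 without scramble 3 replicate 2, and 0.63 with the scramble lines exchanged.

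Part of the knockout difference lay in blocks of neighbouring genes. In the gene order of the GRCh38.p14 assembly, 13150 of the 13792 genes above the floor filled 263 windows of 50 neighbours, and 642 left over at the ends of chromosomes were in no window. There were 9 windows with medians beyond those of all 1000 random gene orders, in the same direction, in both KO5 and KO6. Both lines were set against the same scramble arrays, so their agreement is in part built in. The window from CHST7 to PPP1R3F on chromosome X had a median of -0.49 in each knockout line against scramble, and the window from GAGE10 to AMER1 on the same chromosome -0.39 in KO5 and -0.43 in KO6. The window from PGAM1 to HPS6 on chromosome 10 stood at -0.23 in each line. Higher medians were found in 4 windows of chromosome 4, led by that from TIGD2 to NEUROG2 (0.43 in KO5, 0.34 in KO6), and in 2 of chromosome 1, from LDLRAD1 to ACADM (0.31 and 0.26) and from FOXJ3 to MAST2 (0.24 and 0.20). No window lay beyond the random orders in scramble against wild type. PAGE5, PAGE2, PAGE2B, SSX1, TIMP1 and the demethylase gene KDM5C lie in the lower X windows, and AFF1, LARP7 and LEF1 in the higher chromosome 4 windows.

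**Figure D5:**
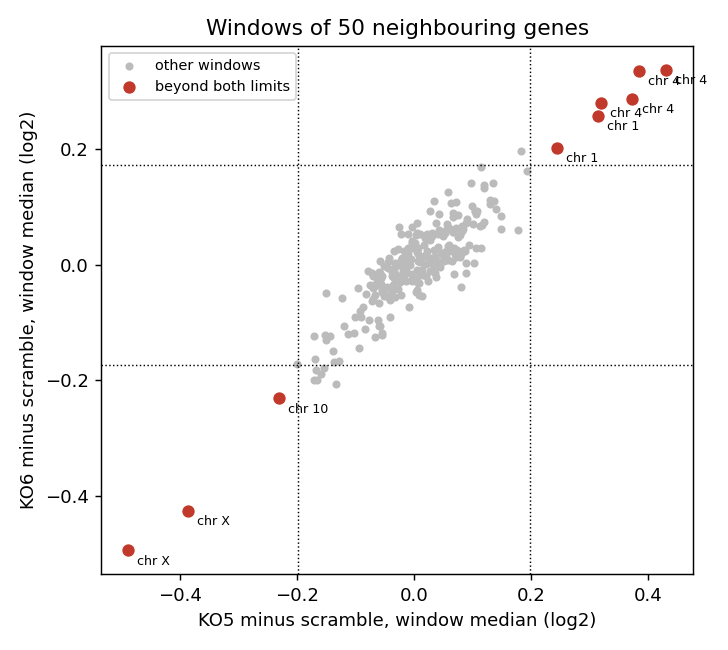
Median log2 difference from scramble of 263 windows of 50 neighbouring genes, in KO5 (horizontal) and KO6 (vertical); dotted lines mark the largest median among 1000 random gene orders. The 9 red windows lie beyond both limits, from -0.49 on chromosome X to 0.43 on chromosome 4.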

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

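The tests of a library deposited more than once and of the poly-A spike-ins were chosen only after the result was seen, as was leaving out 3 deviating arrays (wild type 1, KO6 replicate 1, scramble 3 replicate 1). A sample far from the others of its arm was found in 13 sets of 4 arrays, 11 of them among 207 sets of a gene and an arm, and chance marks about 1 in 20 such sets. MAGEC2 read 10.51 on KO6 replicate 1 against 10.27 to 10.30 on the other knockout arrays. On the same array MXRA8 read 9.08 against 9.31 to 9.35, SLC14A1 5.90 against 6.10 to 6.13, LRRC30 6.66 against 6.25 to 6.30, and the SD over all transcripts was 1.98 against 2.01 to 2.02. On scramble 3 replicate 1 FABP5 read 5.45 against 6.25 to 6.30, NRIP2 6.76 against 6.46 to 6.48, and the SD over all transcripts was 1.94 against 2.01. The remaining ones were SPANXD on KO5 replicate 2 (12.41), PRKD3 on wild type 3 (10.07), GDI2 on wild type 1 (10.26), NCR3LG1 on wild type 4 (6.38) and JMJD6 on wild type 1 (10.31 against 10.21 to 10.23). By array, KO6 replicate 1 held 5 of the 13, scramble 3 replicate 1 held 3 and wild type 1 held 2.

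Control rows outside the comparisons carried a signal on 1 array. The poly-A spike-ins Lys, Phe, Thr and Dap, bacterial transcripts added to the RNA before labelling, lay 5.02, 5.53, 5.39 and 4.82 log2 units above the mean of the other 11 arrays on scramble 3 replicate 1. On those 11 arrays Lys read 5.79 to 6.10 and Phe 6.02 to 6.43, near the background floor, so their differences are not exact. Thr read 6.27 to 7.11 and Dap 7.97 to 8.54 there. A brighter array or raised background would lift the negative controls in raw signals, and their median after RMA differed by -0.049. As commonly run, RMA subtracts background and evens out signals between arrays, so this value cannot decide the question. The hybridisation controls BioB, BioC, BioD and Cre were higher by 0.65, 0.63, 0.52 and 0.26 and the smallest rise of the spike-ins was 4.82, values that less sample RNA or more spike-in in the labelling reaction may explain. No biological explanation was tested.

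Rows left out as controls also differed between the knockout and both control arms: 194 of the 2555 with numeric names and 87 of the 3186 with other control names, by up to 1.88 and 1.18 on the log2 scale. What these rows measure is not given in the sources used here.

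The knockout and control arrays differ alike in both knockout lines. Of 35 splits of the 8 arrays into 4 and 4, 1 of 35, the real one, gave as many calls, with 3687 clusters for knockout against scramble and 3332 against wild type, and 0 in the highest other split. This share treats arrays of a line as exchangeable, which they are not if a line differs as a whole. Only 3 splits of knockout against scramble keep the lines whole, and 7 against wild type keep the knockout lines whole, too few for a share under 0.05. For scramble against wild type the real split gave 28 and the highest other 0, also 1 of 35 with 7 that keep the scramble lines whole, and the calls fell to 0 with the line as a fixed term. These counts used a correlation estimated on a subset of clusters. Values of a single library deposited more than once would be identical, an SD of 0, and the smallest SD between a KO5 and a KO6 array was 0.858 of that between the scramble 7 arrays, which argues against identical copies. Repeated arrays of the same RNA were not tested, and the smallest SD between the lines, 0.15, was below the 0.16 between the KO5 arrays. The 3 deviating arrays are not the source either, since 3379 clusters differed from both controls without them.

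A founder cell or subclone common to both knockout lines is a candidate explanation for part of the difference. The test, set before its result was seen, asked for at least 5 windows of neighbouring genes shifted as blocks in both lines, and 9 were found, with none in scramble against wild type. Because both lines were set against the same scramble arrays, they are not independent checks of each other. Blocks of this kind may come from a copy number that the cells of both lines share, which expression alone does not show. An effect of losing JMJD6 stays open beside it, as no group of the design separates it from line origin.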

How the results depend on the processing

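Leaving out the 3 arrays that deviate together (wild type 1, KO6 replicate 1, scramble 3 replicate 1), array quality weights and leaving out the genes of shifted windows were chosen only after the data were seen. JMJD6 stayed lower under every alternative run, between -0.98 and -0.91 against scramble and between -0.87 and -0.80 against wild type when single arrays were left out. In the order knockout against scramble, against wild type and against both, averaging each line before the test gave 2013, 833 and 664 clusters, leaving out KO5 gave 1724, 1562 and 985 and leaving out KO6 gave 1786, 1660 and 1031, where fewer samples enter. A minimum difference of 1 on the log2 scale gave 197, 202 and 175, and 0 for scramble against wild type. Without scramble 3 or scramble 7, knockout against wild type gave 5883 and 5778. The estimated correlation within lines was then -0.13 and -0.20, against -0.02 with all arrays. Without the 3 deviating arrays, knockout against wild type gave 5455 and both controls 3379, and with array weights 5712 and 3161, with 1 cluster for KO6 against KO5. Both arrays of a line of 2 received the same weight, 0.31 in scramble 3 and 0.98 in KO6. The weights therefore do not set the deviating replicates of these lines apart from their partners. The cause of the higher counts was not tested. Genes outside the shifted windows alone gave 3354, 3021 and 1796.

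Scramble against wild type moved from its 27 clusters: 0 with the line as a fixed term, with line averages, and without KO5 or KO6; 313 without scramble 3, 1073 without scramble 7, 165 with quantile normalization, 155 without dim clusters, 365 with a trended and robust eBayes, 463 without the 3 deviating arrays and 380 with array weights; the cause was not tested. The replicate number pairs only some of the samples. Of 20 pairs of arrays with the same number in different lines, 6 had deviations correlated over 0.1, with r from -0.05 to 0.46. Replicate 1 of wild type correlated with replicate 1 of KO6 (0.45) and of scramble 3 (0.46), and these with each other (0.41). In lines of 2 arrays the deviations mirror each other, so the 20 pairs are not separate checks. With the replicate block, knockout against wild type gave 2081, both controls 1263 and scramble against wild type 0, with 3 gene lists in the last, and knockout against scramble stayed within 1.5 times.

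With single arrays left out, counts ranged from 1827 to 4671 for knockout against scramble, 1191 to 5741 against wild type, 786 to 2967 against both, 0 to 593 for scramble against wild type, 0 to 0 for KO6 against KO5 and 0 to 2822 for scramble 7 against scramble 3. Where a line was left with 1 array, it was assumed to vary like the other lines. The line-pair correlations ranged from 0.46 to 0.78, and from 0.63 to 0.80 with the scramble lines exchanged. Called lists ranged from 9 to 14 for knockout against scramble, 13 to 17 against wild type and 0 to 7 for scramble against wild type. An estimated correlation left 3, 9 and 0 lists, ranks gave 10, 12 and 2, with elongation and unfolded protein response gained against scramble (0.0392 each) and against wild type (0.0281 and 0.0267), where antigen presentation was gained too (0.00405), and without dim clusters knockout against wild type had 11. The 6 lists of scramble against wild type became 3 with fixed lines, line averages or without scramble 3, 2 without KO6, on quantile normalization, on ranks, without the 3 deviating arrays and with array weights, and 1 without KO5 or without scramble 7. Without the 3 deviating arrays the calls lost were, against scramble, leukocyte (0.254), antigen presentation (0.0704) and DNA replication (0.0609); against wild type histones (0.270), leukocyte (0.181), luminal (0.157) and p53 (0.0794); and for scramble against wild type histones and cholesterol (0.236 each) and ribosomal proteins and p53 (0.202 each). MYC, not called against scramble or wild type, changed sign: -0.073 without scramble 3 and from -0.021 to 0.17 with single arrays left out against scramble, and -0.041 without KO5 against wild type. Over all alternatives, values of named genes against scramble kept direction and call in 5353 cases, lost the call in 350 and gained it in 64; against wild type these were 2394, 40 and 6, against both 665 kept, and for scramble against wild type 942, 243 and 40. Clusters under the floor of 6.13 limit what can be seen at low signal.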

Other observations

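No test in this part was chosen after its result was seen; the lists are those fixed in advance, and none named here passed the preset test of knockout against scramble. Genes for the uptake of apoptotic cells, a process once attributed to JMJD6 itself, rose at 4 of 18 members and fell at 3, or the same counts adjusted over the list alone with a median of 0.01 and a mean of -0.05 (limma adjusted p = 0.752). The receptor kinase MERTK fell by 0.93 (SE 0.09), LRP1 fell by 0.82 (SE 0.08) and the cholesterol exporter ABCA1 rose by 0.73 (SE 0.08). Integrins rose at 4 of 17 and fell at 3, the same adjusted over the list alone, with ITGA10 at -1.15 (SE 0.10), ITGB8 at -0.83 (SE 0.09) and ITGA6 at 0.47 (SE 0.06), a median of 0.08 and a mean of -0.02 (limma adjusted p = 0.875). Matrix proteases and their inhibitors fell at 7 of 26 and rose at 3, or 8 and 4 adjusted over the list alone, with MMP1 at -1.37, MMP14 at -0.78 (SE 0.07), TIMP1 at -0.77 (SE 0.08) and TIMP3 at 4.03 (limma adjusted p = 0.303). Genes linked to lung metastasis of this cell line rose at 5 of 19 and fell at 5, the same adjusted over the list alone, with a median of -0.05, a mean of 0.07, the decoy receptor IL13RA2 at 2.53 (SE 0.18, 1 of 4 scramble arrays over the floor) and ID3 at 0.94 (SE 0.08) (limma adjusted p = 0.694). Of 22 apoptosis genes 2 rose and 3 fell, also when adjusted over the list alone, led by the death ligand TNFSF10 (TRAIL) at 2.16 (SE 0.10), with BID at -0.80 (SE 0.09) (limma adjusted p = 0.593).

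Of 14 Notch genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.04, mean -0.04) and of 20 Wnt genes 3 rose and 2 fell (also adjusted over the list alone). HES1 fell by 1.13 (SE 0.09) and the ligand JAG1 rose by 0.94 (SE 0.09), and among the Wnt genes RNF43 rose by 1.10 (SE 0.12), WNT5A by 1.04 (SE 0.12, at least 1.28-fold) and LEF1 by 0.90 (SE 0.13), while WNT7B fell by 0.70 (SE 0.12); the lists had limma adjusted p-values of 0.696 and 0.593. THBS1, an inhibitor of angiogenesis, rose by 1.17 (SE 0.08), and PGF, a vascular growth factor, fell by 0.66 (SE 0.07), in a list with 3 of 19 higher and 7 lower, the same adjusted over the list alone (limma adjusted p = 0.550). MHC class II genes rose at 3 of 8 and fell at 2, the same adjusted over the list alone, with HLA-DRB1 at 0.74 (SE 0.08) and CD74 at -0.52 (SE 0.07) (limma adjusted p = 0.638). Of the JmjC and related oxygenases, the family of JMJD6, none of 29 rose and 5 fell, also 5 adjusted over the list alone, with KDM5C at -0.90 (SE 0.09), in a window of X chromosome genes that was lower in both knockout lines, and 4 of the 29 in shifted windows (limma adjusted p = 0.269). Transcription elongation genes rose at 3 of 16, or 4 adjusted over the list alone, with MEPCE at 0.68 (SE 0.11), LARP7 at 0.88 (SE 0.17) and AFF1 at 0.54 (SE 0.09) (limma adjusted p = 0.107). Splicing factors rose at 4 of 24 and fell at 1, or 4 and 2 adjusted over the list alone, with SRSF11 at 0.42 (SE 0.07) (limma adjusted p = 0.405). SRSF11 lies in a window of chromosome 1 genes that was higher in both knockout lines. Protein arginine methylation genes rose at 3 of 10 and fell at 1, or 4 and 2 adjusted over the list alone, with WDR77 at 0.47 (SE 0.11) (limma adjusted p = 0.694). Without scramble 3 replicate 2 the calls of SRSF10, SRSF6, SRSF3, PRMT1, PRMT9, PRMT6, KDM7A, JARID2 and ALKBH5 in these lists were lost, with a limma adjusted p from 0.0667 (SRSF10) to 0.225 (ALKBH5).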
